A study of Homo sapiens with 24 samples.

How the data were processed

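RNA of 24 cultures of human blood cells was labelled by in vitro transcription and hybridised to 1 Affymetrix array each, per the labels' protocols. The cultures came from 4 donors per cell type, and each donor gave 1 culture with vehicle and 1 with 20 uM rolipram, both of 4 h. CLL samples were mononuclear cells of patients, and normal B and T cells had been purified with magnetic beads, per the labels.

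The authors deposited 1 table of intensity values for 54675 probe sets in 24 arrays. The submitters' processing notes name RMA, with no version or role. The deposited intensity values are on a linear scale, from 0.1 to 16146.2, and 8.36% of them lie under 1, which is not the log2 scale that RMA usually writes. The background correction and summarisation behind them are not given in the sources used here. The array medians are nearly equal, at 15 to 15.7. The test had been planned for log2 values. Since the values are linear they were turned into log2(intensity + 16), a pseudocount chosen after seeing the range of the values and before any test. Fold changes are on that scale, which understates the change of dim genes, and pseudocounts of 1 and 64 were tried as alternatives. Background against signal cannot be told apart per array from these values.

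Probe sets were named through the platform annotation given with the table. Of these, 41097 had 1 gene symbol, 1801 several and 11777 none. For 41043 of the first kind the symbol was updated through the gene number. Only probe sets with 1 symbol name a gene, and a gene was represented by its probe set with the highest mean over the 24 arrays. A probe set was kept if at least 4 of 24 arrays were at or above 15.3, the median of the table. The 62 Affymetrix control probe sets, XIST and Y-linked genes (95 probe sets) were left out. This left 13525 genes.

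The rolipram effects in CLL, B and T cells and the differences between them came from 1 fit of all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had the donor as a block, a treatment effect in each cell type, 1 spread shared by the cell types and 9 residual degrees of freedom. Vehicle arrays were compared in a fit of the 12 vehicle arrays, also with 9 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The pairing comes from the labels, which give the donor of each array. B and T donors of the same number were not treated as 1 person. Arrays of the same donor deviated together from their group means in CLL (r from 0.58 to 0.74 across genes) and T cells (0.44 to 0.61), but in B cells r ran from -0.35 to 0.31.

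Lists of genes for 23 pathways, families and cell types were fixed before the data were examined, and the 22 response and marker lists were tested with limma's camera (preset correlation 0.01, adjusted over the lists of a comparison), with camera at an estimated correlation and with fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes. The lists were cAMP and CREB targets, cyclic nucleotide phosphodiesterases, cAMP signalling machinery, BCL2 family, glucocorticoid receptor and targets, NF-kB targets, cytokines and chemokines, chemokine receptors and adhesion, cell cycle and MYC, B cell receptor signalling, T cell receptor signalling, heat shock and stress response, interferon-stimulated genes, circadian clock, markers of B cells, T cells, NK cells, monocytes, platelets, erythroid cells and plasma cells, CLL-associated genes, and housekeeping genes, which were counted only. RNA quality was followed with the actin and GAPDH control probe sets and exact sign-flip permutation tests over donors.

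The genes named were set by a rule fixed in advance. In each rolipram comparison it took the 10 largest rises and 10 largest falls among called genes that moved the same way in all 4 donors, or the 5 smallest p-values where no gene passed. It added the PDE4 genes, up to 4 genes of each list with the smallest p, 5 per direction for each difference between cell types and 8 per direction for each vehicle comparison. Immunoglobulin and T cell receptor segments, HLA genes, XIST, Y-linked genes and provisional gene names were not named. The text names a part of that set. PDE4C did not pass the filter on dim probe sets.

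The fits were tested on simulated data for the 13525 genes, with 200 changed genes and 5 simulations per comparison. In CLL cells 16.8, 68.4, 92.8 and 96.8% of genes changed by 0.5, 1, 1.5 and 2 log2 units were recovered, none with the wrong sign, and 6.40% of calls were false. When the simulation gave the cell types 1 common spread, false calls were 5.29% in CLL, 3.89% in B and 4.01% in T cells. With each cell type's own spread they were 69.8% in B cells, 8.18% in T cells, 34.6% for CLL against B, 2.56% for CLL against T, 35.2% for B against T, 19.4% for vehicle CLL against B and 15.4% for vehicle B against T. These shares hold for 200 changed genes and do not carry over to other counts of called genes. The shared spread is too small for B cells, whose pairs varied more than those of the other cell types. These simulations take each gene's spread in each cell type, estimated from 4 donors, as exact.

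Alternatives fixed in advance were the fit without the donor block, only the arrays of the cell types compared, no filter and a stricter filter on dim probe sets, quantile normalization, median centring, the mean of a gene's probe sets, each probe set on its own, an intensity trend with a robust prior, array weights, rolipram in place of vehicle arrays, and leaving out each donor in turn. Those added after seeing the data were the pseudocounts, the T cell arrays alone without T replicate 2, marker scores or the actin signal as covariates, and the list tests without each donor in turn. Replicates are separate donors per the labels.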

Results

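Rolipram is an inhibitor of type 4 cyclic AMP phosphodiesterases, the enzymes encoded by the PDE4 genes that break down the second messenger cyclic AMP (cAMP). The series measured what this drug did to transcript levels in 3 kinds of human blood cells. The first was mononuclear cells from the blood of patients with B cell chronic lymphocytic leukaemia, called CLL cells here. The others were magnetically purified B cells, which the labels call resting, and T cells, both from healthy donors. Cells of each donor were cultured for 4 h with 20 uM rolipram or with the solvent alone (vehicle), and RNA of each culture was hybridised to 1 Affymetrix array. There were 4 donors per cell type and 24 arrays in all. Array medians lay between 15 and 15.7 intensity units, and the number of arrays limits the precision. No 2 arrays held identical values. In a principal component analysis the first component took 50.4% and the second 24.7% of the variance.

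In CLL cells rolipram changed 618 of 13525 genes, of which 315 rose and 303 fell. The largest rise was in the orphan nuclear receptor gene NR4A3, 14.4-fold (log2 change 3.84 ± 0.45, SE, n = 4 donors, limma adjusted p = 0.000626). Its relative NR4A2 rose by 3.15 ± 0.40 on the log2 scale, and the cAMP response element modulator CREM by 3.48 ± 0.42. PDE4A, which encodes a target of the drug, rose 4.70-fold (2.23 ± 0.38, adjusted p = 0.00429). The largest fall was in CD79B, which encodes a signalling chain of the B cell receptor, at -2.19 ± 0.26 (adjusted p = 0.000665).

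Among the other large rises in CLL cells were DUSP4 (3.07 ± 0.46), which encodes a phosphatase of MAP kinases, and ZNF331 (2.96 ± 0.39), which encodes a zinc finger protein. BMP6, a secreted growth factor, rose by 2.95 ± 0.47, and the AP-1 subunit gene FOSL2 by 2.76 ± 0.46. LDLRAD4, a negative regulator of TGF-beta signalling, rose by 2.44 ± 0.25. SOCS3, a feedback inhibitor of cytokine signalling, rose by 2.30 ± 0.44. The other large falls were TMT1A at -2.00 ± 0.14, the B cell transcriptional coactivator POU2AF1 at -1.79 ± 0.21, NAPSB at -1.72 ± 0.19 and PTPN6 at -1.70 ± 0.23. PTPN6 encodes the phosphatase SHP-1. The RNA sensor TLR7 fell by 1.67 ± 0.28, VIPR1, a receptor for vasoactive intestinal peptide, by 1.62 ± 0.35, and FCRL5 changed by -1.50 ± 0.34. OAS1 fell by 1.48 ± 0.21 and TCL1A, a coactivator of the kinase AKT, by 1.46 ± 0.22. Each of these genes passed an adjusted p of 0.05 and moved the same way in all 4 CLL donors, as did 615 of the 618 genes. At least a 2-fold change was seen in 225 genes, 141 of them up and 84 down.

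**Figure D1:**
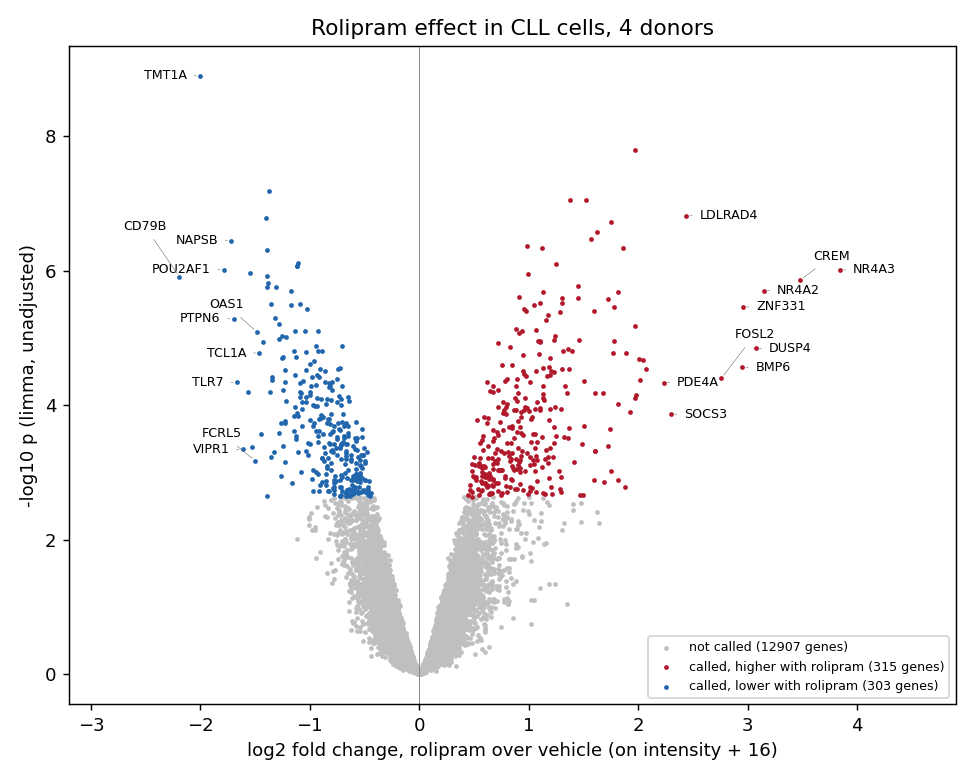
Each point is 1 of the 13525 genes tested in CLL cells, with the log2 fold change of rolipram over vehicle on the horizontal axis and the -log10 of the unadjusted limma p on the vertical axis. Red points are the 315 genes that rose, blue points the 303 that fell and grey points the genes that did not pass, with NR4A3 farthest to the right at 3.84 and CD79B farthest to the left at -2.19.

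The count for CLL cells used a spread shared by the 3 cell types. It was 248 without CLL replicate 1, 215 without CLL replicate 3 and 275 without CLL replicate 4. It was 1531 from the CLL arrays alone, 2540 with array weights, 158 without the donor block, 388 with a pseudocount of 1 and 254 with the actin 3 prime to 5 prime signal of each array in the fit.

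Part of the genes that respond to cAMP rose in CLL cells. Of 36 measured targets of cAMP and its transcription factor CREB, 10 rose, none fell and 26 did not pass, and adjusted over the list alone 15 passed. RGS1, a regulator of G protein signalling, rose by 1.97 ± 0.28 beside NR4A3, CREM and NR4A2. The list stood apart from other genes with limma's camera test (adjusted p = 5.21e-06), but not with an estimated correlation (adjusted p = 0.647 with an estimated correlation). Of 15 measured cyclic nucleotide phosphodiesterases, PDE4A rose and 14 did not pass, with 3 passing when adjusted over the list alone. That list had a camera adjusted p of 0.0390, and adjusted p = 0.163 with an estimated correlation. fry, which asks only whether a list moves on balance, called this list (adjusted p = 0.00729) but not the cAMP and CREB targets (0.157). The camera call of the phosphodiesterases was lost without CLL replicate 1 (0.172), CLL replicate 2 (0.0808) or B replicate 2 (0.0505). PDE4B had a log2 change of 0.82 ± 0.26 (limma adjusted p = 0.0996) and PDE4D of 0.48 ± 0.21 (limma adjusted p = 0.257), so neither passed, although both were higher with rolipram in all 4 donors. PDE4B passed with the CLL arrays alone and with array weights. Of 28 measured genes of the cAMP signalling machinery, PRKAR2A, a regulatory subunit of protein kinase A, rose (0.48 ± 0.11), and PKIG, an inhibitor of that kinase, fell (-0.66 ± 0.17). With adjustment over the list alone 6 passed, and camera gave an adjusted p of 0.519.

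Part of the B cell receptor genes and B cell markers fell in CLL cells. Of 22 measured genes of B cell receptor signalling, 9 fell, 1 rose and 12 did not pass, and adjusted over the list alone 13 passed. Beside CD79B and PTPN6, the kinase gene PRKCB fell by 1.36 ± 0.18 and the inhibitory Fc receptor gene FCGR2B by 1.13 ± 0.16. Camera gave an adjusted p of 1.51e-05 for this list, and adjusted p = 0.163 with an estimated correlation. Of 13 measured B cell markers 5 fell and none rose, and adjusted over the list alone 9 passed. They included VPREB3 (-1.38 ± 0.17) and BANK1 (-1.24 ± 0.19). This list had a camera adjusted p of 1.59e-07 and kept its call with an estimated correlation (adjusted p = 0.0259 with an estimated correlation), the only one of the 22 tested lists to do so in CLL cells. That last call was lost when a donor of another cell type was left out, at 0.0703 without B replicate 3, 0.0601 without T replicate 2 and 0.0509 without T replicate 4. In the same arrays the actin 3 prime minus 5 prime signal was 0.24 ± 0.22 log2 units higher with rolipram (SD, n = 4). Of 16 measured genes associated with CLL, FMOD (-1.21 ± 0.18), TCL1A and FILIP1L (-0.91 ± 0.23) fell and CTLA4 (1.14 ± 0.21) rose. Adjusted over the list alone 8 passed, and camera gave an adjusted p of 0.0628, or 0.0383 without CLL replicate 1, 0.0497 without CLL replicate 4 and 0.0493 without B replicate 1. With fry the CLL-associated genes had an adjusted p of 0.000109, as did the B cell markers, and the B cell receptor list had 0.00259. Among 7 plasma cell markers the transcription factor gene IRF4 rose (1.15 ± 0.30), with 3 passing when adjusted over the list alone and a camera adjusted p of 0.945.

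Stress genes rose in part. Of 20 measured heat shock and stress response genes, 3 rose and 17 did not pass, and adjusted over the list alone 4 passed. The mitochondrial chaperone pair HSPD1 and HSPE1 rose by 1.62 ± 0.17 and 1.45 ± 0.18, and HERPUD1, a gene of the endoplasmic reticulum stress response, by 0.79 ± 0.13. Camera gave an adjusted p of 0.0114 for this list (0.0638 without CLL replicate 1), adjusted p = 0.647 with an estimated correlation, and fry did not call it (0.0994). In the BCL2 family of 17 genes, the pro-apoptotic members BCL2L11 (1.09 ± 0.17) and BAK1 (0.46 ± 0.12) rose, with 4 passing when adjusted over the list alone (camera adjusted p = 0.352). The pro-apoptotic member BMF was lower with rolipram (-0.77) and the anti-apoptotic member BCL2A1 higher (0.65), neither passing over all genes. The family thus did not shift in 1 direction. Of 21 measured glucocorticoid genes, the glucocorticoid receptor gene NR3C1 (1.31 ± 0.17) and DUSP1 (2.02 ± 0.34) rose and TXNIP fell (-1.16 ± 0.29). Adjusted over the list alone 5 passed (camera adjusted p = 0.228).

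Camera called none of 4 lists of immune signalling in CLL cells. Of 24 NF-kB targets 2 rose and 4 fell, and adjusted over the list alone 8 passed (camera adjusted p = 0.795). CD83 (1.11 ± 0.16) and REL (0.89 ± 0.16) rose, while LTB (-1.32 ± 0.18) and NFKBIA (-0.70 ± 0.10), which encodes an inhibitor of NF-kB, fell. Of 29 cytokine and chemokine genes IL10 rose (1.06 ± 0.25) and LTB fell, with 2 passing when adjusted over the list alone (camera adjusted p = 0.352). Of 26 genes for chemokine receptors and adhesion, GPR183, which guides B cell migration, rose by 1.78 ± 0.23. In that list CCR7 (-0.81 ± 0.14), ITGB7 (-0.96 ± 0.18) and ITGB1 (-0.80 ± 0.16) fell, with 4 passing when adjusted over the list alone (camera adjusted p = 0.216). Of 24 interferon-stimulated genes, OAS1, OAS3 (-1.43 ± 0.21) and OAS2 (-0.57 ± 0.15) fell and none rose over all genes, with 4 passing in either direction when adjusted over the list alone (camera adjusted p = 0.352). MX2 of that list was higher with rolipram (0.80) but did not pass over all genes.

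Camera called none of the remaining lists in CLL cells. Of 24 cell cycle genes MCM6, a subunit of the replicative helicase, rose (1.16 ± 0.16), with 4 passing in either direction when adjusted over the list alone (camera adjusted p = 0.352). PCNA (0.89) and CDKN1A (1.17), an inhibitor of the cell cycle, were higher with rolipram and CCND3 (-0.80) lower, none of them passing over all genes. Of 25 genes of T cell receptor signalling CTLA4 and NFATC2 (0.54 ± 0.13) rose, and the same number passed when adjusted over the list alone (camera adjusted p = 0.686). Of 15 circadian clock genes CRY1 rose (0.52 ± 0.13) and BHLHE40 (-1.04 ± 0.17) and DBP (-0.81 ± 0.19) fell, with 3 passing when adjusted over the list alone (camera adjusted p = 0.945). Among markers of other blood cells, limma called 0 of 12 T cell, 0 of 11 NK cell, 0 of 15 monocyte and 0 of 5 erythroid genes, over all genes and adjusted over the list alone. Camera gave these lists adjusted p-values of 0.771, 0.795, 0.352 and 0.945. Of 9 platelet markers MYL9 fell (-0.47 ± 0.12), and 1 passed when adjusted over the list alone (camera adjusted p = 0.795). The median and mean log2 change differed in sign for the NF-kB (0.03 and -0.05), T cell receptor (-0.07 and 0.05), clock (0.07 and -0.02), erythroid (-0.01 and 0.02), plasma cell (-0.12 and 0.03) and cell cycle lists, the last with a median just under 0 and a mean of 0.16. Of 12 housekeeping genes, which were not tested as a list, none passed, over all genes or adjusted over the list alone.

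**Figure D2:**
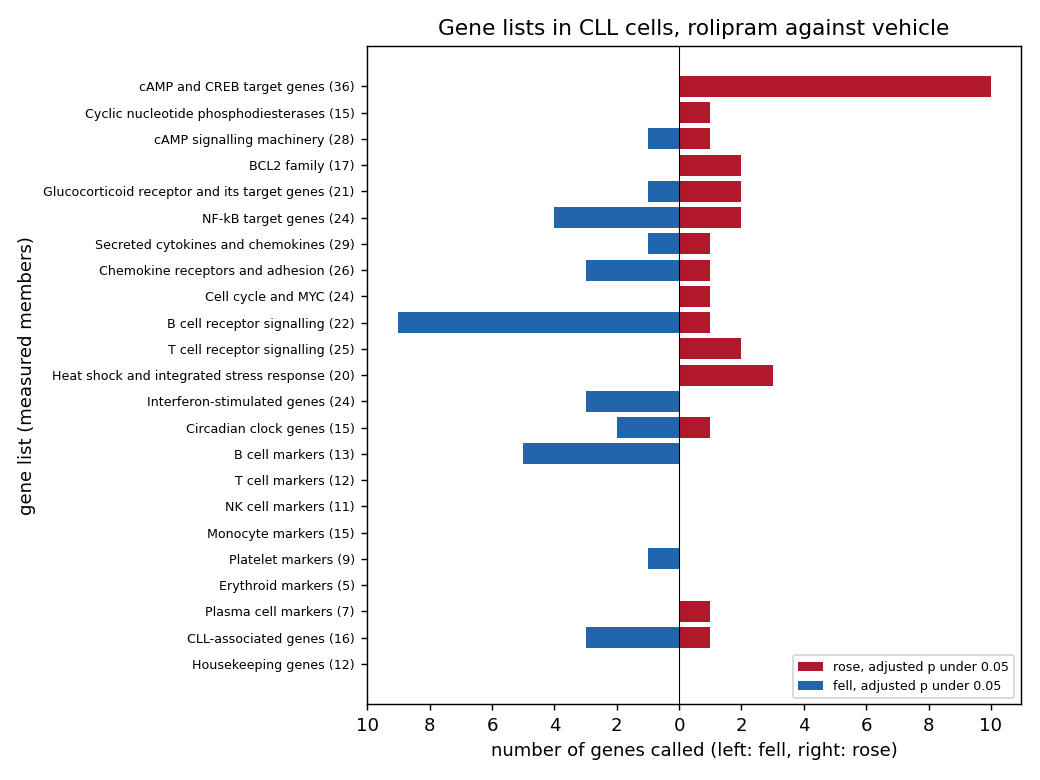
Bars show, for each gene list fixed in advance, how many measured members rose (right, red) or fell (left, blue) in CLL cells with rolipram at a limma adjusted p under 0.05, with the number measured in brackets. The cAMP and CREB targets have 10 rises and no fall, and the B cell receptor list has 9 falls and 1 rise.

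In normal B cells no gene passed the limma test after rolipram, with 1822 genes at an unadjusted p under 0.05, and the changes differed between the labelled donor pairs. DONSON (0.82 ± 0.12, SE, n = 4) and GPC1 (1.24 ± 0.19) were among the genes with the smallest p, and at an adjusted p of 0.0628 they did not pass. CD79B had a log2 change of -1.17 ± 0.26 (adjusted p = 0.151). PDE4A was at 0.36 ± 0.38, PDE4B at 0.51 ± 0.26 and PDE4D at 0.37 ± 0.21, with adjusted p-values of 0.687, 0.401 and 0.446. Of the 618 genes called in CLL cells, 43.9, 76.4, 58.1 and 77.7% moved the same way as in CLL in the 4 B cell donors. Markers of other blood cells differed between the 2 arrays of B cell donors. In replicates 1 to 4 the median log2 change was 1.60, -0.63, -0.46 and 0.21 for 15 monocyte markers and 1.30, 0.45, -1.32 and 0.17 for 11 NK cell markers. It was 0.55, 0.56, -0.61 and 0.31 for 12 T cell markers and 0.15, -0.81, 1.40 and 0.14 for 9 platelet markers.

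Camera called 4 of the 22 lists in B cells, and 0 with an estimated correlation. The cAMP and CREB targets had a median log2 change of 0.40 (camera adjusted p = 0.00151, and adjusted p = 0.663 with an estimated correlation). The B cell receptor genes had a median of -0.21 (0.0173), the B cell markers one of -0.20 (0.0312) and the platelet markers one of 0.43 (0.0312). Each of these also had an adjusted p of 0.663 with an estimated correlation. Within these 4 lists no member passed over all genes, and adjusted over the list alone 0, 2, 3 and 1 passed. Each of the 4 calls was lost without some donor. Without B replicate 2 the cAMP list had a camera adjusted p of 0.722, the receptor list 0.161 and the B cell markers 0.0948, and the monocyte markers were called (0.00385). Without B replicate 3 the B cell markers had 0.0821 and the platelet markers 0.983, with a platelet median of -0.13. Without that replicate camera called the T cell (0.00182) and NK cell markers (9.13e-05), and the T cell receptor (0.0148), heat shock (0.0460) and clock lists (0.0472). The platelet call was also lost without B replicate 1 (0.0573), and the receptor call without B replicate 4 (0.0506). Counts in B cells rested on which donors entered: 311 genes were called without B replicate 1, 1281 without B replicate 3 and 1 without B replicate 4. The median residual SD within donors was 0.330 on the log2 scale in B cells against 0.149 in CLL and 0.159 in T cells, and in simulations with 200 changed genes and these unequal spreads 69.8% of B cell calls were false. Array weights gave 706 genes, and the B cell arrays alone gave 0.

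In normal T cells no gene passed the limma test after rolipram either, and 247 genes had an unadjusted p under 0.05. The cAMP targets NR4A2 (1.36 ± 0.40, SE, n = 4), CREM (1.36 ± 0.42) and SIK1 (1.08 ± 0.36) were higher in 3 of the 4 T cell donors and lower in the other, with an adjusted p of 1.00 each. PDE4A was at 0.74 ± 0.38, PDE4B at 0.64 ± 0.26 and PDE4D at 0.54 ± 0.21, none of them passing. The share of the 618 CLL genes that moved as in CLL was 71.0, 75.1 and 76.2% in 3 donors and 27.2% in the other.

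Camera called 5 of the 22 lists in T cells, and 0 with an estimated correlation. The cAMP and CREB targets had a median log2 change of 0.22 (camera adjusted p = 0.00155, and adjusted p = 0.857 with an estimated correlation). The phosphodiesterases (median 0.16), glucocorticoid genes (0.08), B cell receptor genes (-0.11) and T cell receptor genes (0.10) each had a camera adjusted p of 0.0460. Their adjusted p-values with an estimated correlation were 0.507, 0.679, 0.679 and 0.686. No member of these lists passed over all genes or adjusted over the list alone. Without T replicate 2 the cAMP list had a median of 0.41 and a camera adjusted p of 6.11e-16 (adjusted p = 0.258 with an estimated correlation), with 1 member up over all genes and 12 passing adjusted over the list alone. The cAMP call was lost without T replicate 1 (0.259), T replicate 3 (0.151) or T replicate 4 (0.163). Of the other 4 calls none held throughout. The B cell receptor list had 0.350 and the T cell receptor list 0.165 without T replicate 2, and without T replicate 1 all 4 calls were lost, at 0.337 for the glucocorticoid list and 0.235 for the others. Leaving out T replicates 3 or 4, CLL replicate 1 or B replicates 2, 3 or 4 also ended 3 or 4 of these 4 calls, at adjusted p-values from 0.0509 to 0.176. Camera called the NK cell markers without B replicate 1 (0.0445) or B replicate 3 (0.0137) and the B cell markers without T replicate 3 (0.0190). Without T replicate 2 limma called 3 genes, and with array weights it called 195.

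**Figure D3:**
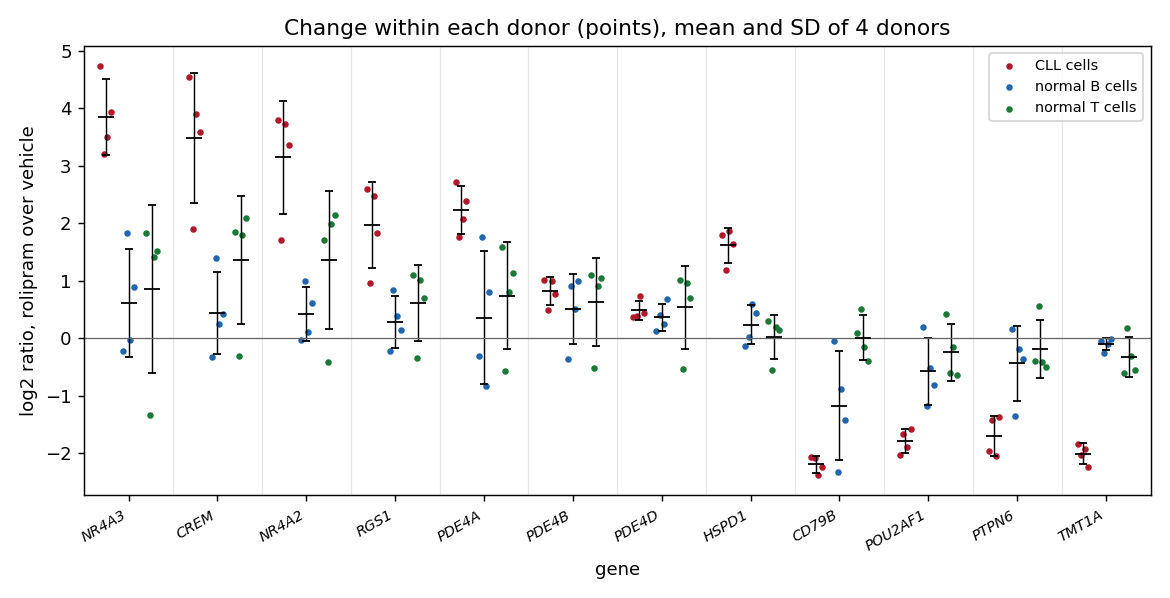
Points are the log2 ratios of rolipram over vehicle within each donor for 12 genes, with CLL cells in red, normal B cells in blue and normal T cells in green, and bars give the mean and SD of the 4 donors. All CLL points lie above 0 for the first 8 genes and below 0 for the last 4, whereas B and T cell donors lie on both sides of 0 for most of them. Most of the 12 genes were chosen for their change in these CLL donors, so this contrast is not a test of a difference between cell types.

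The response to rolipram differed between CLL and normal B cells for 30 genes. It was more positive in CLL for 17, including LDLRAD4 (difference of log2 changes 1.96 ± 0.35, SE, limma adjusted p = 0.0363) and CDK5R1 (1.79 ± 0.23), an activator of the kinase CDK5. TBC1D27P (1.71 ± 0.30), KLF10 (1.68 ± 0.25), a TGF-beta-inducible transcription factor, and LPCAT1 (1.60 ± 0.24), an enzyme of phospholipid remodelling, were also among them. It was more negative in CLL for 13 genes, including PRDM16-DT (-1.91 ± 0.34), TMT1A (-1.91 ± 0.19), FMOD (-1.64 ± 0.25), the ATP-gated channel gene P2RX7 (-1.54 ± 0.24) and VPREB3 (-1.37 ± 0.24). The differences of PDE4A (1.87 ± 0.53, adjusted p = 0.177), CREM (3.04 ± 0.60, 0.0663), NR4A3 (3.23 ± 0.64, 0.0663) and CD79B (-1.02 ± 0.37, 0.315) did not pass. Of the lists, only the B cell markers differed with camera (median -0.64, 1 of 13 lower and 0 higher over all genes, 5 passing adjusted over the list alone, adjusted p = 0.00562), and not with an estimated correlation (adjusted p = 0.358 with an estimated correlation). The call was lost without B replicate 1 (0.0670). Camera called the cAMP targets without CLL replicate 2 (0.0455), B replicate 2 (0.000728) or T replicate 2 (0.0496). Without B replicate 2 it also called the B cell receptor (0.00399), monocyte (0.00187) and platelet lists (0.000992), and without B replicate 3 the cytokine (0.0244), T cell (0.00151), NK cell (0.000142) and monocyte lists (0.0398).

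The count of 30 genes depends on how the spread was estimated. In simulations with 200 changed genes and the cell types' own spreads 34.6% of calls were false, the CLL and B cell arrays alone called 1 gene, array weights called 327, a pseudocount of 1 called 0 and one of 64 called 124, and without the donor block 3 were called. It was 11, 1 and 3 without CLL replicates 1, 3 and 4. It was 49, 207 and 7 without B replicates 2, 3 and 4, and 12, 13 and 11 without T replicates 1, 3 and 4. An intensity trend with a robust prior called 54.

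Between CLL and normal T cells the response differed for 38 genes, with 20 more positive and 18 more negative in CLL. LDLRAD4 (2.32 ± 0.35, SE, limma adjusted p = 0.0215), CDK5R1 (2.18 ± 0.23) and KLF10 (1.94 ± 0.25) were again in the first group, with CDK2AP1 (1.79 ± 0.31) and MOB1B (1.68 ± 0.21). CD79B (-2.20 ± 0.37), NAPSB (-1.93 ± 0.26), TMT1A (-1.68 ± 0.19), the B cell surface receptor gene CD180 (-1.50 ± 0.25) and NCF1 (-1.44 ± 0.21) were in the second. The differences of PDE4A (1.49 ± 0.53, adjusted p = 0.370), CREM (2.12 ± 0.60, 0.189) and NR4A3 (2.98 ± 0.64, 0.0832) did not pass. Camera called 5 lists. The cAMP and CREB targets (adjusted p = 0.000967) and the heat shock genes (0.00309) were more positive in CLL. The B cell receptor genes (0.000608), the B cell markers (1.91e-06) and the CLL-associated genes (0.00503) were more negative. Of these 5, the B cell markers alone held with an estimated correlation (adjusted p = 0.0428 with an estimated correlation), and the others had adjusted p-values of 0.872, 0.584, 0.323 and 0.0753 in the order given. Without T replicate 2 the cAMP list had a camera adjusted p of 0.396, with a median of 0.01, and the heat shock list one of 0.108. For the B cell markers the call with an estimated correlation was lost without any of the 4 CLL donors (0.0591, 0.0555, 0.0510 and 0.0545), without B replicates 3 and 4 (0.0993 and 0.0768) and without T replicates 2, 3 and 4 (0.0643, 0.0795 and 0.1001). Over all genes 0 of 36, 2 of 20, 2 of 22, 2 of 13 and 0 of 16 members passed, and adjusted over the list alone 7, 3, 10, 6 and 4.

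The count of 38 also moved with the donors and settings. It was 9, 2 and 10 without CLL replicates 1, 3 and 4. It was 59, 88 and 18 without B replicates 2, 3 and 4, and 2, 5, 9 and 5 without T replicates 1, 2, 3 and 4. The CLL and T cell arrays alone called 332, array weights 831, a stricter filter on dim probe sets 60, the mean of all probe sets 22, an intensity trend with a robust prior 65, a pseudocount of 1 called 4 and one of 64 called 137, and the fit without the donor block 2.

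Between normal B and T cells limma called 0 differences, with 834 genes at an unadjusted p under 0.05, and camera called 0 lists, with 3 at an unadjusted p under 0.05. Without B replicate 3 the count was 23, and 35.2% of calls were false in simulations with 200 changed genes. No gene was called in more than 1 cell type, since B and T cells had none. Across genes, which are not independent replicates, the rolipram effects in CLL and B cells had a Pearson r of 0.31 and a Spearman rho of 0.28, and those in CLL and T cells an r of 0.21 and a rho of 0.12. The cell types share no arrays. Of the 618 CLL genes, the mean change had the CLL direction for 474 in B cells and 421 in T cells.

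In vehicle-treated cells 6320 genes differed between CLL and normal B cells, 3466 higher and 2854 lower in CLL. The genes with the largest excess in CLL included TGFBI (50.4-fold, log2 5.66 ± 0.33, SE, n = 4 per group, limma adjusted p = 1.13e-07), the inhibitory receptor gene CTLA4 (32.4-fold) and the transcription factor gene LEF1 (25.4-fold). The beta globin gene HBB was 132-fold higher in CLL samples, which were mononuclear cells and not purified. CCDC88A (22.3-fold), ADTRP (20.9-fold), ALDH5A1 (20.6-fold) and RPA1 (17.2-fold) followed. COL1A1 was 107-fold lower in CLL than in B cells, and the immediate early genes FOSB (93.1-fold) and FOS (48.2-fold) were also lower. HES1 (78.0-fold), PMEPA1 (56.3-fold) and LMNA (49.0-fold) were lower too, as were the rolipram-responsive genes NR4A3 (73.9-fold) and DUSP4 (50.5-fold).

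Genes of cAMP, NF-kB and stress responses were lower in vehicle-treated CLL than in vehicle-treated B cells. Most members of these lists were also higher in vehicle-treated B than T cells, as given below. Low levels are therefore not shown to be particular to CLL cells, and vehicle-treated CLL and T cells were not compared. Of the cAMP and CREB targets 28 of 36 were lower and none higher, EGR1 by 39.2-fold and NR4A1 by 26.4-fold among them. Of the NF-kB targets 20 of 24 were lower, ICAM1 by 10.1-fold and NFKB1 by 8.65-fold among them, and of the heat shock genes 19 of 20, with HSPH1 15.5-fold lower. TNF was 8.26-fold, IL6 35.5-fold and MYC 34.6-fold lower. The cytokine and chemokine list went both ways, with 3 of 29 higher and 10 lower in CLL. So did the cell cycle and MYC list, with 6 of 24 higher and 8 lower. Of the phosphodiesterases 5 of 15 were lower, PDE4A by 6.69-fold and PDE4D by 3.66-fold. Of the CLL-associated genes 12 of 16 were higher, CD5 by 8.19-fold and CD200 by 5.46-fold. T cell markers were higher in CLL samples for 6 of 12 genes (CD3D 3.75-fold), NK cell markers for 6 of 11 (PRF1 4.37-fold), monocyte markers for 6 of 15 (CD14 4.47-fold, S100A8 6.07-fold) and erythroid markers for 3 of 5. Adjusted over the list alone, 28, 20, 19, 4, 13, 6, 6, 6 and 3 members of the cAMP, NF-kB, heat shock, phosphodiesterase, CLL-associated, T cell, NK cell, monocyte and erythroid lists passed in either direction. In the cytokine and cell cycle lists 12 and 14 did.

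Vehicle-treated B and T cells differed in 6700 genes, 3126 higher and 3574 lower in B cells, and the lineage markers followed the labels. All 13 measured B cell markers were higher in B cells and all 12 T cell markers lower, with the same counts adjusted over the list alone. MS4A1, which encodes CD20, was 95.1-fold higher in B cells (log2 6.57 ± 0.54, SE, n = 4 per group, limma adjusted p = 6.26e-07). RUBCNL (71.2-fold), HES1 (67.3-fold), EBF1 (62.6-fold), FOSB (60.2-fold), POU2AF1 (51.0-fold), TBC1D9 (50.2-fold) and CD83 (49.4-fold) were higher too, as were PAX5 (34.3-fold) and CD79A (45.3-fold). CD3D (68.8-fold), BCL11B (66.2-fold), KLRB1 (57.0-fold), GIMAP7 (50.4-fold), GIMAP2 (45.4-fold), TRAT1 (45.0-fold), NELL2 (42.9-fold), FYB1 (41.5-fold) and CD3E (19.4-fold) were lower in B cells. The cAMP and CREB targets were higher in B than in T cells for 28 of 36 genes (30 passing adjusted over the list alone), with EGR1 48.0-fold higher. Of the NF-kB targets 17 of 24 were higher in B cells and 0 lower (17 passing adjusted over the list alone). Of the heat shock genes 16 of 20 were higher and 1 lower (19 passing adjusted over the list alone). PDE4A was 9.83-fold and PDE4B 4.27-fold higher in B cells, and PDE4D was 5.53-fold lower.

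Signs of RNA quality were set beside the groups. The actin 3 prime minus 5 prime signal was 0.24 ± 0.22 log2 units higher with rolipram in CLL (SD, n = 4, exact two-sided sign-flip permutation p = 0.25), 0.24 ± 0.20 in B cells (exact p = 0.25) and 0.06 ± 0.27 in T cells (exact p = 0.75). The smallest p that 4 donors allow is 0.125, so none could pass, and over the 6 tests run with actin and GAPDH the adjusted values were 0.75 or higher.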

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

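The tests of treatment labels, of other cells' markers, of genes already high before rolipram and of the actin signal below were chosen after the results were seen, whereas the splits of samples were planned.

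Some values stood apart from the other donors of their group by Dixon's criterion, in 14 of 159 groups of 4 examined, where chance gives about 5%. In CLL donors these were the lowest log2 ratio of DUSP4 (1.73) and of ZNF331 (1.63), the ratio of NFKBIA at -0.88 and that of BANK1 at -1.01. In T cell donors they were the ratios of PDE4B at -0.51, CREM at -0.30 and SIK1 at -0.87, the list medians of cAMP and CREB targets at -0.52, of NF-kB targets at -0.18 and of B cell markers at 0, and a correlation with the CLL effect of -0.52. In B cell donors the median of the clock genes was -0.34 in 1 donor, and the actin 3 prime minus 5 prime signal of 1 rolipram array was 0.80. The median intensity of 1 T cell vehicle array was 15.

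The response to rolipram differed between CLL and B cells for 30 genes and between CLL and T cells for 38, by the test of the difference itself. Among called genes that the naming rule allows, the largest differences between CLL and B cells were LDLRAD4 (1.96), CDK5R1 (1.79), TBC1D27P (1.71), KLF10 (1.68) and LPCAT1 (1.60), and PRDM16-DT (-1.91), TMT1A (-1.91), FMOD (-1.64), P2RX7 (-1.54) and VPREB3 (-1.37). Between CLL and T cells those among such genes were LDLRAD4 (2.32), CDK5R1 (2.18), KLF10 (1.94), CDK2AP1 (1.79) and MOB1B (1.68), and CD79B (-2.20), NAPSB (-1.93), TMT1A (-1.68), CD180 (-1.50) and NCF1 (-1.44). Among 5920 probe sets with no gene name, which no comparison above used, 155 changed in CLL cells with limma, 103 up and 52 down.

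Other assignments of the samples were tried for each count. For the 3 rolipram effects, the treatments within donors can be exchanged in 8 ways, too few for a share under 0.05. In CLL cells the real assignment called 618 genes and the highest of the others 0 (1 of 8 called as many), and 24 further splits parting 2 of the pairs called at most 2. In B cells the real assignment called 0 and another called 2107 (8 of 8 called as many), and splits parting 2 pairs called up to 2711. The shared spread is too small for B cells, which can itself raise such counts, and a structure among the B cell samples was not tested. In T cells the real one called 0 and another 4 (8 of 8). For CLL against B the real split called 30 genes and the highest of the others 1 (1 of 35 splits), and for CLL against T 38 and 0 (1 of 35). As 1 of 35 is the smallest share this test can give, it argues against chance assignment within this fit but does not exclude it. With the CLL and B cell arrays alone, where the spread leaves out the T cells, the count for CLL against B was 1. Vehicle CLL against B (6320, highest other 1, 1 of 35) and vehicle B against T (6700, highest other 818, 1 of 35) gave the same share. For B against T the real count of 0 leaves this test nothing to decide, since each of the 35 splits calls at least as many (35 of 35, highest other 1), and the same holds for the counts of 0 in B and T cells.

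After rolipram 1 of the 4 T cell donors moved against the other 3 across all genes. An exchange of treatment labels with no other difference was argued against, since 0 of 4 donors had both arrays at the exchanged levels over the 36 cAMP and CREB targets. In 1 of 4 both arrays had a mean level of these targets above every vehicle array of the other 3, and their rolipram arrays were not part of this comparison. An exchange in cells that already had raised levels stays open, and the low share of genes moving as in CLL goes with it. A large excess of other blood cells in the vehicle over the rolipram array of that donor is argued against. The highest median of 6 marker lists, vehicle minus rolipram, was only 0.289 log2 units. Other cells present alike in both of its arrays would not show in this test. A donor difference was not tested.

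Normal B cells gave no called gene, although 2 of 4 donors moved largely as CLL cells did. A share of other blood cells that differed between a donor's arrays is a candidate explanation. With monocyte and T cell marker scores in the fit 867 genes were called (338 up, 529 down), and 2 of 100 random list pairs gave as many (highest 889). Random genes need not move together as these markers do (estimated correlation 0.41 for monocyte and 0.33 for T cell markers), so this result does not single out other blood cells. B cell calls in the planned fit were also often false in simulations. Magnetic purification is meant to remove such cells, but their markers differed between the arrays of B cell donors, as given above. Vehicle-treated B cells held S100A8 at 181 ± 253, CD14 at 25.2 ± 27.8 and CD3D at 40.6 ± 45.0 intensity units (SD, n = 4). Of the 867 genes, 65 were also called in CLL in the same direction, where independent lists share 19.7, and 3 in the opposite one. Genes already above the CLL rolipram level did not clearly respond less, with a difference in response ratio of -0.0148 (95% bootstrap interval over genes, not donors, -0.0671 to 0.0687) when 1 pair of donors set the level and 0.131 (0.0431 to 0.201) when the other did, so this cannot be told apart. An exchange of labels within 1 donor cannot be told apart either, since the measures point to different donors. The lowest share of genes moving as in CLL was 43.9% over the 4 donors, in B replicate 1, where 15 of 36 cAMP and CREB targets were higher with rolipram. In B replicate 3 that share was 58.1%, but only 8 of 36 targets were higher, and exchanging the treatments of this donor called 2107 genes. An exchange of arrays between donors was not tested and stays open. On the third principal component (4.16% of the variance) the rolipram array of B replicate 1 was at -18.0. The vehicle arrays of replicates 1, 2 and 4 were at -16.4, -28.0 and -16.1. The vehicle array of replicate 3 was at 10.9, and the rolipram arrays of replicates 2, 3 and 4 at 13.3, 7.40 and 17.0.

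In CLL cells 5 of 13 B cell markers fell. A lower share of CLL cells would raise the markers of other cells, but the median change of 38 T, NK and monocyte markers was -0.126 (95% bootstrap interval over genes -0.201 to -0.00645). That interval resamples the genes, which can move together, and does not measure the spread between donors. In CLL donors 1 to 4 the monocyte median was -0.24, -0.43, -0.21 and 0.14, and the T cell and NK cell medians were negative in each. With the actin signal in the fit the median change of the 13 B cell markers was -0.785 against -0.836 without it, and 5 fell. The same fit called 254 genes in CLL cells against 618 without the signal. The actin signal was higher with rolipram in 3 of 4 CLL donors, so the fit can hardly separate it from the treatment. The median thus changed little, but whether a shift in the 3 prime to 5 prime signal adds to the fall of these markers stays open. That rolipram lowers these transcripts in CLL cells remains a hypothesis, found and tested on the same samples.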

How the results depend on the processing

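The pseudocounts, marker scores, actin signal, T cell arrays without T replicate 2 and list tests without each donor were chosen after the data were seen, and the other settings were planned. Values are numbers of called genes, and the cause was not tested unless stated. Without the donor block (no pairing) the counts were 158 in CLL, 6 in B cells, 3 for CLL against B and 2 for CLL against T, and this fit changed no other count of called genes by over 1.5 times. With only the arrays compared they were 1531 in CLL, 1 for CLL against B and 332 for CLL against T, since the spread then leaves out the other cell types. Array weights gave 2540 in CLL, 706 in B, 195 in T, 327 for CLL against B and 831 for CLL against T. A pseudocount of 1 gave 388 in CLL, 7 in B, 0 for CLL against B with limma (1371 at an unadjusted p under 0.05) and 4 for CLL against T, and one of 64 gave 124 and 137 for the differences of CLL from B and T. A stricter filter gave 60 for CLL against T. The mean of all probe sets gave 1 in T cells and 22 for CLL against T. Every probe set on its own, with 33831 tested, gave 1198 in CLL, 9 in B, 56 for CLL against B, 14701 for vehicle CLL against B and 15594 for vehicle B against T. An intensity trend with a robust prior gave 54 and 65 for CLL against B and T. The T cell arrays alone without T replicate 2 gave 1, the marker scores 867 in B cells, and the actin signal 254 in CLL, of which 244 were among the 618.

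Leaving out each replicate in turn gave 215 (without CLL replicate 3) to 922 (without B replicate 3) genes in CLL, 0 to 1281 (without B replicate 3) in B cells and 0 to 3 (without T replicate 2) in T cells. The ranges were 1 (without CLL replicate 3) to 207 (without B replicate 3) for CLL against B, 2 to 88 (without B replicate 3) for CLL against T and 0 to 23 (without B replicate 3) for B against T. For vehicle CLL against B the range was 5441 to 6590 and for vehicle B against T 5812 to 6843. The 618 genes in CLL were all among those called without B replicate 3.

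Of the 22 lists, camera called 5 in CLL, 4 in B and 5 in T cells. An estimated correlation left 1, 0 and 0, fry gave 4 in CLL (3 of them called by camera), 0 in B and 0 in T cells, and the fit without the donor block gave 2 in B and 1 in T cells. Leaving out each replicate gave 4 to 6 lists in CLL, 2 (without B replicate 2) to 7 (without B replicate 3) in B and 0 (without T replicate 1) to 6 (without B replicate 1) in T cells. Quantile normalization, median centring and no filter moved no count of called genes by over 1.5 times, and the list tests were not run under them. For 145 pairs of a named gene and a comparison, other settings gave 1518 values on the same side of the threshold and in the same direction, 126 that lost the call, 18 that gained it and 0 in the opposite direction. Leaving out replicates gave 1549, 181, 9 and 1, the last being PDE4A in B cells without B replicate 2 (-0.11), which had not passed. The range of PDE4A over left-out replicates in B cells was -0.11 to 0.75 (without B replicate 3). With 8.36% of intensities under 1, dim genes limit what can be detected.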

Other observations

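The tests of starting levels below were planned, and the median of other cells' markers was taken after the results were seen.

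Lists of genes that set CLL apart from normal B cells had median changes with rolipram toward the B cell level. Starting levels and responses were taken from different CLL donors, so that a gene could not enter a list through the noise of the same arrays. The 200 genes highest in vehicle-treated CLL over B cells had a median log2 change of -0.265 and -0.260 with rolipram in the CLL donors not used to choose them. Random lists of the same size and mean intensity had medians between -0.0414 and 0.0518 and between -0.0520 and 0.0353 (95% of 10000 lists), so both values lay below all 10000. The 200 genes lowest in CLL had medians of 0.241 and 0.230, above all random lists, whose ranges were -0.0456 to 0.0479 and -0.0524 to 0.0328. The random lists were not matched on the level in vehicle-treated CLL cells. Genes chosen as lowest in CLL can start near the floor set by the pseudocount, with less room to fall than the matched genes. How much of the upward medians comes from this was not tested. Random lists treat genes as independent, although responding genes can move together, so these ranges do not measure the spread between donors. Both choices of CLL donors were set against the same B cell arrays and are not independent repeats. These medians (-0.260 and 0.230 as the values nearer to 0) are those that the hypothesis needs, that rolipram shifts genes higher in CLL than in normal B cells downward on balance and genes lower in CLL upward. They do not say how many of the genes changed. Camera did not call the fixed list of CLL-associated genes (adjusted p = 0.0628), whereas fry, which does not compare a list with other genes, did (adjusted p = 0.000109). Part of the upward medians may be the rise of cAMP and CREB targets described above. Of these, 28 of 36 were lower in vehicle-treated CLL than in B cells, and 10 of 36 rose with rolipram. Their share in the lists of 200 genes was not counted. The B cells had been purified and the CLL samples had not, so part of the starting difference may be one of cell purity and handling, which this test does not separate. Markers of other blood cells share the direction: part of the T cell, NK cell and monocyte markers were higher in vehicle-treated CLL samples than in B cells, and the median change of these 38 markers with rolipram in CLL samples was -0.126 (95% bootstrap interval over genes, not donors, -0.201 to -0.00645), with none passing. Other cells in the CLL samples thus stay open as a source of part of these medians.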
